A study of Mus musculus with 17 samples.

How the data were processed

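Whole-genome expression was measured on 17 Agilent one-colour arrays of mouse bone marrow HSCs. Per the labels' protocols, 1000 cells a sample were sorted from pools of 4 to 5 mice, RNA was extracted with magnetic beads, amplified as a whole transcriptome and labelled with Cy3. Such amplification from few cells adds spread between replicates and can compress or distort ratios. Groups and replicate numbers came from the sample labels. The CD41 sort comprised 3 CD41-negative and 3 CD41-positive arrays, and the LT-HSC set 3 wild-type arrays at 2 months, 2 CD41-KO arrays at 2 months, and 3 arrays of each genotype at 12 months.

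Per the file headers, the deposited scanner files hold spot intensities from Agilent Feature Extraction with a one-colour gene expression protocol, with probe positions on mouse build mm9. The processed intensity in these deposited files was background-subtracted and spatially detrended within each array, with faint spots set to a surrogate value, and was not normalized between arrays. The deposited value table holds the authors' log2 values of the same arrays. How the authors made it is not given in the sources used here. Its columns correlated with normexp-corrected, quantile-normalized scanner values at 0.9997 or more on every array, and their medians were 9.46 to 9.48 for the CD41 sort and 8.07 to 8.08 for the LT-HSC arrays, so both sets appear to have been normalized apart. It is a log2 scale without centring, and the authors' exact method and offset remain unknown.

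Control spots and spots marked as outliers by the scanner software (104 to 264 an array) were left out, and 59305 gene spots remained. The signal was divided by the array's 75th percentile, which lay between 450 and 2382, and taken to log2. Spots of a probe were averaged, giving 55681 probes. A probe was kept if it was well above background on all arrays of at least 1 group, which left 53958 probes in the CD41 sort and 50441 in the LT-HSC set. A gene was represented by its probe with the highest mean, and 10096 genes had several probes. Of the probes, 26300 were named through their accession in a table of mouse RefSeq genes (assembly GRCm38.p6, used for names only), which changed 2839 symbols, and 29381 kept the name in the file, for 36499 gene names in all. No genome sequence was used here, so whether a probe lies in an exon or a UTR was not analysed.

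Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The CD41 sort was fitted alone (35474 genes, of which 90 lacked a value on some array). The LT-HSC set was fitted with 1 coefficient per group and a shared spread (33591 genes, 19 with a missing value), and the difference of the genotype effects between ages was tested as an interaction. Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, under which no list passed in any comparison. With it, 7, 1, 3, 4, 4 and 2 lists had an unadjusted p under 0.05 in the CD41 sort, the genotype effect at 2 and 12 months, the age effect in wild-type and CD41-KO cells and the interaction. Of 703 listed genes 692 were on the array. Tables were handled with data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, block fits used statmod 1.5.0 and figures matplotlib 3.10.9.

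The groups, comparisons, lists, main alternatives and the rule for named genes were fixed before the data were examined. Centring on the median, a 2-fold threshold, leaving out X and Y genes and the block in the LT-HSC arrays alone were added afterwards. The tests on explanations were added then too. The rule took Itga2b, then the 10 highest and 10 lowest log2 fold changes among called genes with a gene symbol whose groups did not overlap, then the 4 members with the smallest p of each called list, then a fixed set shown in every comparison (Itgb3, Vwf, Selp, Slamf1, Pf4, Gata1, Cd48, Flt3 and Mpo). Some genes that the rule takes are not reported here. The interaction used only its highest and lowest genes, without the overlap condition. The lists were megakaryocyte and platelet, erythroid, granulocyte and monocyte, lymphoid, long-term HSC, multipotent progenitor, cell cycle, quiescence, HSC ageing, interferon, immediate early, p53 and DNA damage, antigen presentation, oxidative phosphorylation, glycolysis and hypoxia, ribosomal protein, integrin, cytokine receptor and sex-linked genes, and markers of B cells, T and NK cells, macrophages, neutrophils, mast cells with basophils and eosinophils, endothelium and stroma.

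Replicates of a group correlated at 0.993 to 0.998 in the CD41 sort and 0.976 to 0.987 in the LT-HSC set, and no files were identical. These correlations ran over the tested genes with a value on every array, each represented by its brightest kept probe. In the LT-HSC set each replicate number of the labels lay on its own slide and scan (slides 2 to 4), and deviations from the group means of same-numbered arrays correlated at 0.349 to 0.726, all above 0.1, so the numbers pair these arrays. The labels do not say what a number shares. Values with the replicate number as a block are given where they change a call or move a count by over 1.5 times. The alternatives were quantile normalization, normexp (offset 50) with quantile normalization, the deposited log2 values, other filters on dim probes, the mean of a gene's probes, eBayes with trend and robust settings, array weights, the replicate number as a block, the slide as a random block, only the 2 groups compared, other set sizes and leaving out each array.

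On simulated data with 200 changed genes per comparison, drawn with seed 1, the sign was right for every recovered gene. Genes changed 2-fold were recovered at 77.6% in the CD41 sort, 22.4% and 56.7% for genotype at 2 and 12 months, 44.8% for age in each genotype and 13.4% for the interaction. Genes changed 4-fold were recovered at 97.0%, 80.3%, 84.8%, 87.9%, 92.4% and 54.5% in the same order. Between 0 and 9 unchanged genes were called. A list shifted by 0.5 was called in each comparison, and at most 1 other list was. The simulated genes and arrays were drawn independently. These figures therefore do not measure false calls where genes or same-numbered arrays move together. In the real comparisons 5.16% to 58.8% of the tested genes were called, far more than the 200 changed here. What passes a Benjamini-Hochberg threshold depends on that share, so the recoveries and false calls describe the simulated setting only.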

Results

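Gene expression was measured on 17 one-colour microarrays of haematopoietic stem cells (HSCs) sorted from mouse bone marrow. CD41 is the integrin alpha-IIb chain, encoded by Itga2b, which pairs with the beta-3 chain (Itgb3) to form the fibrinogen receptor of platelets. In the first set of arrays, lineage-negative Sca-1-positive c-Kit-positive (LSK) cells lacking Flt3 were split into CD41-negative and CD41-positive HSCs, with 3 arrays each. In the second set, long-term HSCs (LT-HSCs), gated as LSK cells without CD48 and with CD150, came from wild-type mice (3 arrays at 2 months of age, 3 at 12 months) and CD41-knockout (CD41-KO) mice (2 arrays at 2 months, 3 at 12 months). Each array held the amplified RNA of 1000 sorted cells from a pool of 4 to 5 mice. The labels do not say whether replicates came from separate pools, so p-values measure only the spread between these samples, which may be technical. Between 96.0% and 98.5% of gene spots were well above background on the CD41 sort arrays and between 82.7% and 93.3% on the LT-HSC arrays, and no spot was saturated. The number of arrays limits the precision.

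Levels are log2 signals relative to the array's 75th percentile, and differences are log2 fold changes ± SE with limma's adjusted p. The median over all genes was 0.17 in the CD41 sort (0.10 to 0.13 under the other scalings), 0.14 for age in CD41-KO mice (0.06 to 0.09) and 0.09 for age in wild-type mice (0.03 to 0.04). It lay between -0.02 and 0.01 elsewhere, so list shifts are given relative to it. Of the lists of genes fixed before the data were examined, 7 passed camera's test in no comparison. Their lowest adjusted p was 0.0519 for granulocyte and monocyte genes, 0.303 for integrins, and 0.478, 0.0924, 0.43, 0.0541 and 0.239 for markers of B cells, T and NK cells, macrophages, neutrophils and endothelium.

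The first comparison asked how CD41-positive HSCs differed from CD41-negative HSCs. Itga2b, measured by a probe placed on mouse build mm9 chromosome 11 from 102319453 to 102319661, stood at 0.69 ± 0.05 (SD, n = 3) in CD41-positive and -0.17 ± 0.11 (SD, n = 3) in CD41-negative HSCs. The difference of 0.86 ± 0.08 passed the test (limma adjusted p = 0.000109). Where in the transcript the probe lies was not analysed here. Pf4, the platelet chemokine platelet factor 4, rose in CD41-positive HSCs by 3.72 ± 0.08, Gata1, the transcription factor of megakaryocytes and erythroid cells, by 1.96 ± 0.09, and Klf1, the erythroid transcription factor, by 1.77 ± 0.10. The water channel gene Aqp1 (2.02 ± 0.14), the P-selectin gene Selp (0.84 ± 0.09) and the von Willebrand factor gene Vwf (0.80 ± 0.08) rose as well. Itgb3 (0.21 ± 0.11, adjusted p = 0.138) did not pass. It did with quantile normalization (0.26, adjusted p = 0.0306), normexp (0.21, adjusted p = 0.0452), the mean of its probes (0.92, adjusted p = 4.38e-05), array weights (0.30, adjusted p = 0.0173) and without CD41-negative replicate 1 (0.30, adjusted p = 0.0375). The tetraspanin gene Cd53 fell by 3.07 ± 0.08, Dntt, the terminal deoxynucleotidyl transferase of lymphoid precursors, by 2.42 ± 0.11, Satb1 by 2.25 ± 0.10, Cd48 by 1.63 ± 0.07, the interleukin-7 receptor gene Il7r by 1.60 ± 0.07, Flt3 by 1.48 ± 0.10 and the myeloperoxidase gene Mpo by 1.17 ± 0.07. Another probe of Flt3 had the opposite sign.

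Of the remaining genes with the largest changes, Foxf2 (2.61), the receptor gene Mrgprd (2.42), the histone gene H4c3 (2.30), Adam8 (2.25), Gal3st2c (2.20), Serp2 (2.13), Zdhhc19 (2.07) and Togaram2 (2.04) were higher in CD41-positive HSCs. Upk3b was not well above background on any CD41-negative array and was at least 2.97-fold higher. Here and below such a bound sets the mean of the brighter group against the higher, per array, of the dim probe's own signal and the lowest signal well above background. On the CD41-negative arrays Foxf2 was well above background on 1 of 3, and Mrgprd, Adam8 and Gal3st2c on 2 of 3. The cathepsin S gene Ctss fell by 3.12, the chemokine gene Ccl3 by 2.60, Mn1 by 2.58, Snn and Cdc40 both by 2.47, Wsb1 by 2.46, the integrin beta-1 gene Itgb1 by 2.45 and the RNA helicase gene Dhx15 by 2.43. The adjusted p of these 17 genes and of the 3 named above from the same ranking, Pf4, Cd53 and Dntt, was at most 0.000409. With normexp background correction, whose added offset compresses the ratios of dim probes, 14 of the 83 called genes chosen by the naming rule had a log2 fold change smaller by over 1.5 times. Of those named here, Foxf2 stood at 1.06, Mrgprd at 1.26, Adam8 at 1.09, Gal3st2c at 1.06, Serp2 at 1.33, Togaram2 at 1.31, Aqp1 at 1.14, Runx1t1 at 1.17, Igfbp5 at 0.54 and Cxcl12 at 0.32. Bounds here and below do not carry over to that scale.

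**Figure D1:**
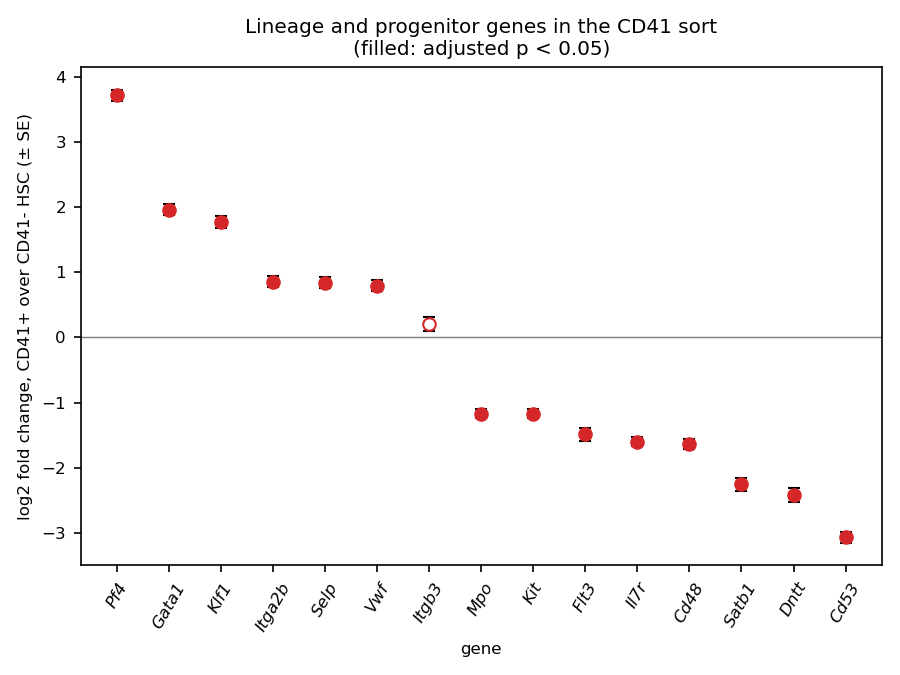
Log2 fold change of 15 lineage and progenitor genes in CD41-positive over CD41-negative HSCs (y axis, points with SE bars, 3 arrays a group). Pf4 stood at 3.72 and Cd53 at -3.07, and the open point, Itgb3, did not pass the test.

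Relative to all tested genes the gene lists moved mostly downwards, with 15 of 25 past camera's test, 3 up and 12 down. In the multipotent progenitor list 0 of 23 genes rose and 21 fell, and its median lay 1.62 below that of all genes (adjusted p = 1.61e-14, and adjusted p = 0.123 with an estimated correlation). In the oxidative phosphorylation list 0 of 41 rose and 28 fell (shift -0.75, adjusted p = 1.73e-12, and adjusted p = 0.123 with an estimated correlation). Examples were Atp5a1 (-1.52 ± 0.09), Cox7b (-1.33 ± 0.08) and Sdha (-1.22 ± 0.08), subunits of the respiratory chain and ATP synthase. In the interferon list 2 of 36 rose and 29 fell (shift -0.75, adjusted p = 2.02e-10, and adjusted p = 0.138 with an estimated correlation), among them the antiviral gene Oas3 (-1.52 ± 0.08) and the guanylate-binding protein gene Gbp3 (-1.50 ± 0.11). In the antigen presentation list 2 of 20 rose and 15 fell (shift -0.81, adjusted p = 1.94e-06, and adjusted p = 0.145 with an estimated correlation), with Psmb8 at -1.19 ± 0.07 and Tapbp at -1.21 ± 0.08. In the HSC ageing list 25 of 42 rose and 5 fell (shift 0.19, adjusted p = 0.0184, and adjusted p = 0.138 with an estimated correlation), with Runx1t1 at 1.82 ± 0.12 and Nupr1 at 1.22 ± 0.08, and Alcam at -1.19 ± 0.08.

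The erythroid list had 18 of 28 genes up and 3 down (shift 0.19, adjusted p = 0.0491), and the stromal list, which includes Igfbp5 (0.86 ± 0.10) and Cxcl12 (0.55 ± 0.08), had 11 of 14 up and 2 down (shift 0.30, adjusted p = 0.0491). Both had an adjusted p of 0.145 with an estimated correlation. The transferrin receptor gene Tfrc (-1.51 ± 0.08) and the carbonic anhydrase gene Car2 (-0.89 ± 0.08) went against the erythroid list. The ribosomal protein (0 up and 26 down of 42, shift -0.52) and cell cycle (8 up and 21 down of 42, shift -0.34) lists had an adjusted p of 4.75e-07 and 0.000818, and of 0.323 for both with an estimated correlation. Pcna, the DNA polymerase clamp, fell by 1.49 ± 0.07 and the replicative helicase genes Mcm5 and Mcm4 by 1.38 ± 0.09 and 1.27 ± 0.07. The glycolysis and hypoxia (2 up and 17 down of 28, shift -0.53, adjusted p = 3.38e-05) and cytokine receptor (6 up and 16 down of 29, shift -0.51, adjusted p = 0.000423) lists had an adjusted p of 0.123 with an estimated correlation. In the latter the receptor genes Il1r1 (-2.05 ± 0.08), Cxcr4 (-1.44 ± 0.08) and Kit (-1.17 ± 0.07) fell. The immediate early list (6 up and 15 down of 29, shift -0.36, adjusted p = 0.00045, and adjusted p = 0.138 with an estimated correlation) held Fos at -1.85 ± 0.09 and Myc at -1.72 ± 0.10. The quiescence (5 up and 12 down of 23, shift -0.67, adjusted p = 0.000858), p53 (7 up and 12 down of 30, shift -0.35, adjusted p = 0.0178) and lymphoid (9 up and 13 down of 34, shift -0.22, adjusted p = 0.0227) lists had an adjusted p of 0.145 with an estimated correlation. Members that fell include Rbl2 (-1.82 ± 0.10), Sesn1 (-2.11 ± 0.08) and Btg2 (-1.44 ± 0.11). In the megakaryocyte and platelet list, which did not pass (adjusted p = 0.0519), 17 of 40 rose and 4 fell. Adjusted over the list alone, the counts were 19 up and 3 down for the erythroid, 0 and 28 for the ribosomal protein list, and as given for the other called lists. The erythroid and stromal calls were lost under each of the 3 other scalings and without CD41-negative replicate 1, the erythroid call also without CD41-positive replicate 1, and the stromal call also without CD41-positive replicate 3. The lymphoid median turned above 0 with array weights or with the mean of a gene's probes, and the latter also ended its call.

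In all, 13396 genes were higher and 7480 lower in CD41-positive HSCs among 35474 tested, of which 648 and 1573 changed 2-fold or more. Probes taken as silent in blood, for olfactory receptors, vomeronasal receptors, intergenic RNAs and other families, moved with the groups. Their genes had a median of 0.26, with 2957 of 5996 higher and 466 lower. Of these, 4581 were intergenic RNAs, whose silence in HSCs was not tested. The genes taken as silent are part of the background of camera's test and of the list shifts, which were not redone without them. All arrays of this comparison lay on 1 slide with each group in its own row, so row and group cannot be told apart.

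The second comparison asked what the loss of CD41 changed in LT-HSCs of 2-month-old mice. Itga2b stood at -1.85 ± 0.58 (SD, n = 2) in CD41-KO and 0.85 ± 0.20 (SD, n = 3) in wild-type arrays, a fall by 2.71 ± 0.30 (adjusted p = 0.000533), by 3.28 on slide 2 and by 2.07 on slide 3. The signal in CD41-KO cells was still well above background. The sources used here do not give the deleted part of the gene, so whether the probe lies in it is not known. Emilin2, an extracellular matrix gene, rose by 3.75 ± 0.15, the phosphodiesterase gene Gdpd3 by 5.51 ± 0.40 and Selp by 1.71 ± 0.19 in CD41-KO cells. Klf2, a zinc-finger transcription factor, fell by 1.96 ± 0.20 and the AP-1 gene Junb by 1.47 ± 0.17. Sex-linked genes also moved with the groups. Xist, the RNA that silences an X chromosome in female cells, stood at 5.28 ± 0.29 (SD, n = 2) in CD41-KO and -2.28 ± 0.16 (SD, n = 3) in wild-type arrays. Of the Y-linked genes, Ddx3y was at least 17.2-fold, Uty at least 6.38-fold and Kdm5d at least 4.94-fold lower in CD41-KO cells. Genotype and this difference in sex-linked genes cannot be told apart at 2 months, so every change given for this comparison may reflect either.

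The 10 highest and 10 lowest genes also included Olfr924 (2.71 ± 0.22) and Hoxd9 (2.69 ± 0.48) above, and Ssty2 (-9.51), Rbmy (-6.50), Orly (-5.83), Ssty1 (-4.86), Olfr877 (-3.34) and Sly (-3.33) below. On the wild-type arrays Gdpd3 was well above background on 2 of 3, and Olfr924 and Hoxd9 on 1 of 3. Of genes not well above background on any wild-type array, Atg9b was at least 4.44-fold, the alkaline phosphatase gene Alpl at least 3.73-fold, Slc8a2 at least 3.59-fold, Glod5 at least 2.30-fold and Egfl6 at least 2.20-fold higher. Olfr881 was at least 26.6-fold lower. In the immediate early list 0 of 29 genes rose and 12 fell, or 17 adjusted over the list alone (shift -0.64, adjusted p = 4.06e-09, and adjusted p = 0.895 with an estimated correlation). Its median was -0.61 on slide 2 and -0.57 on slide 3, and Atf3 (-1.42 ± 0.22) and Klf6 (-1.19 ± 0.21) fell too. In the oxidative phosphorylation list 7 of 41 rose and 0 fell, or 15 and 0 adjusted over the list alone (shift 0.40, adjusted p = 7.48e-07, medians 0.37 and 0.39 on slides 2 and 3), with Ndufb8 at 0.63 ± 0.12. In the cell cycle list 9 of 42 rose and 1 fell, or 14 and 1 adjusted over the list alone (shift 0.35, adjusted p = 0.000281, medians 0.33 and 0.31), with Nusap1 at 1.07 ± 0.13 and Ccne1, cyclin E1, at 0.77 ± 0.11. In the long-term HSC list 8 of 40 rose and 0 fell, or 8 and 1 adjusted over the list alone (shift 0.25, adjusted p = 0.0069, medians 0.19 and 0.30), with the transcription factor genes Mycn at 1.16 ± 0.18 and Hoxb5 at 1.00 ± 0.16. These 3 lists had an adjusted p of 0.895 with an estimated correlation. In the list of sex-linked genes 1 of 5 rose and 4 fell (adjusted p = 0.00061, and adjusted p = 0.873 with an estimated correlation). Of the genes listed for every comparison, Slamf1 (0.91 ± 0.24), Pf4 (0.70 ± 0.15), Vwf (0.68 ± 0.19) and Itgb3 (-0.69 ± 0.17) passed by a small margin (adjusted p from 0.0189 to 0.049). Gata1 (0.43 ± 0.12, adjusted p = 0.051), Cd48 (0.09 ± 0.22), Flt3 (-0.28 ± 0.39) and Mpo (-0.05 ± 0.50) did not, though the mean of the probes of Mpo gave a called rise of 1.5. Gata1 passed with the replicate number as a block (adjusted p = 0.00491), the mean of its probes (0.0403), probes well above background on all arrays (0.048), trend and robust eBayes (0.0368) and without wild-type replicate 2 at 12 months (0.0476).

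In all, 2481 genes were higher and 1492 lower in 2-month CD41-KO cells among 33591 tested (7098 and 5268 with the replicate block), and 1379 changed 2-fold or more. X and Y held 11.8% of the called genes with a mapped probe and 4.53% of those tested, and 3476 of the called genes lay on autosomes. A total of 3307 genes were called when X and Y genes were left out before the fit and the adjustment. The count was 988 without CD41-KO replicate 1, 1970 without CD41-KO replicate 2, 2259 without wild-type replicate 3 and 1043 with only these 2 groups in the fit. With the block 9 lists passed, adding the megakaryocyte (adjusted p = 0.0214), interferon (0.0152), antigen presentation (0.024) and ribosomal protein (0.00111) lists, of which 8, 7, 3 and 1 genes rose and 2, 2, 0 and 0 fell without it, and the call of the long-term HSC list was lost without CD41-KO replicate 1. Of 42 called genes chosen by the naming rule, 24 passed in every setting that tested them. With normexp 16 had a log2 fold change smaller by over 1.5 times, among them Gdpd3 (3.60), Olfr924 (1.23), Hoxd9 (0.92), Selp (0.87), Slamf1 (0.47), Atf3 (-0.94) and Olfr877 (-2.11). With the mean of probes Sly stood at -7.22 and Itgb3 at -0.43.

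**Figure D2:**
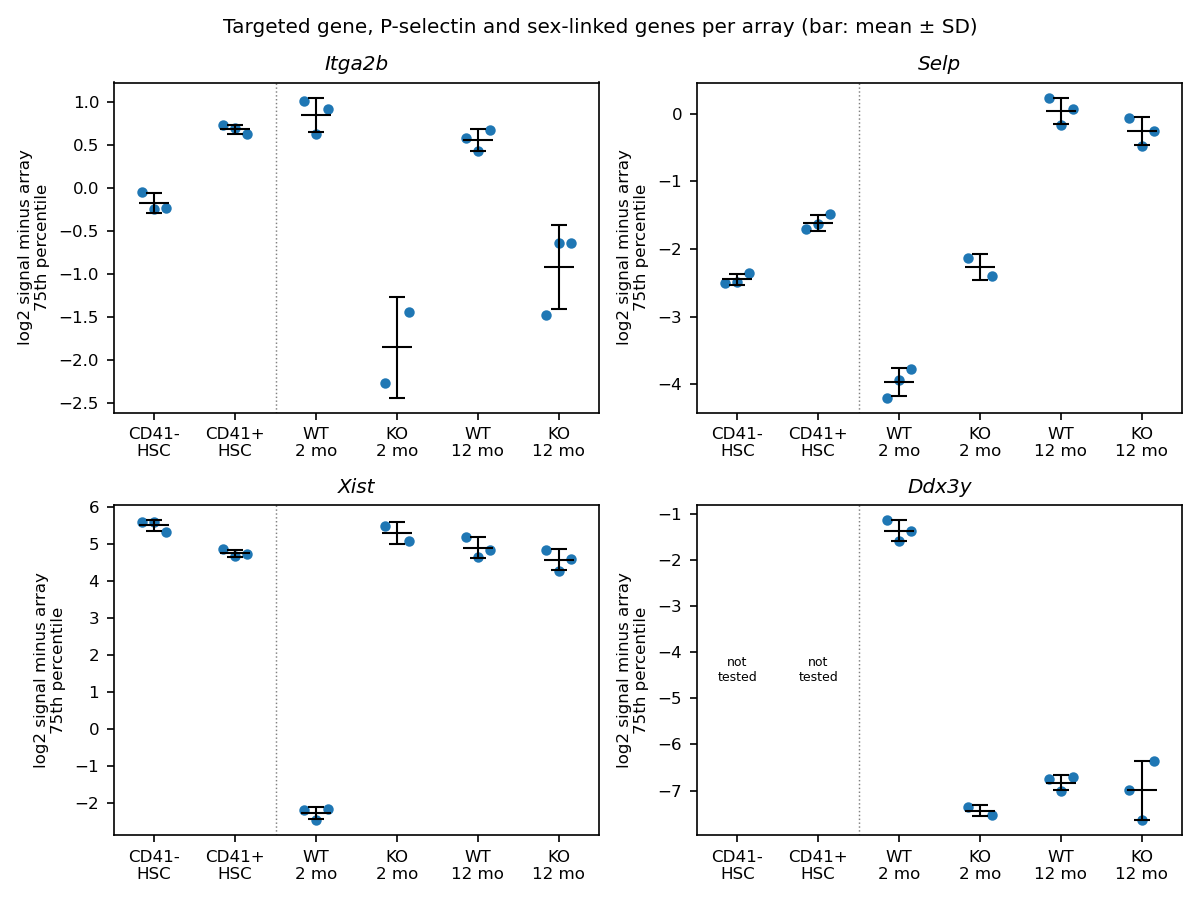
Log2 signal relative to the array's 75th percentile (y axis) of Itga2b, Selp, Xist and a Y-linked gene on each array by group (x axis), with bars for the mean ± SD. Itga2b stood at -1.85 in 2-month and -0.92 in 12-month CD41-KO arrays, below the wild-type arrays, and Xist was low only on the 3 wild-type arrays at 2 months.

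The third comparison asked the same at 12 months of age, where all 6 arrays carried Xist. Itga2b stood at -0.92 ± 0.49 (SD, n = 3) in CD41-KO and 0.56 ± 0.12 (SD, n = 3) in wild-type arrays, a fall by 1.48 ± 0.27 (adjusted p = 0.0157). The difference was -2.06, -1.06 and -1.31 on slides 2, 3 and 4. Without wild-type replicate 1 or 3 it no longer passed (adjusted p = 0.057 and 0.0686). Of eosinophil genes, Prg2, the major basic protein (-2.83 ± 0.11), the eosinophil ribonuclease genes Ear6 (-4.78 ± 0.37) and Ear2 (-1.33 ± 0.12) and the eosinophil peroxidase gene Epx (-1.53 ± 0.21) fell in CD41-KO cells. Prg3 (-0.71, adjusted p = 0.282, and 0.0154 with the replicate block), Ear1 (-0.03, adjusted p = 0.951) and Ear10 (-0.13, adjusted p = 0.533) did not pass. Ear genes are close paralogs, so their probes may share signal. Klf1 fell by 1.30 ± 0.14, the haemoglobin gene Hbb-bt by 1.72 ± 0.24, the thrombospondin gene Thbs1 by 1.43 ± 0.21 and Klf2 by 1.56 ± 0.18. Gdpd3 rose by 5.50 ± 0.36 and Cxcl12, the chemokine that retains HSCs in the marrow, by 1.67 ± 0.12.

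Olfr924 (2.17 ± 0.19), Kif2b (2.08 ± 0.27), Scpep1 (1.94 ± 0.10) and Olfr332 (1.93 ± 0.15) were also among the 10 highest genes. Insm1 was at least 3.65-fold, Skint8 at least 2.90-fold, Etnppl at least 2.56-fold, Resp18 at least 2.23-fold and Arhgef17 at least 1.15-fold higher. P2rx5 (-3.40 ± 0.30), Ccdc54 (-3.05 ± 0.18), Csta2 (-2.68 ± 0.44) and Dhrs7c (-2.66 ± 0.33) were among the 10 lowest, with H2bu2 at least 3.57-fold, Kbtbd7 at least 2.89-fold, Phlda2 at least 2.74-fold and Cd200r4 at least 1.98-fold lower. Of genes measured on part of a group, Gdpd3 was well above background on 1 of 3 and Olfr924 on 2 of 3 wild-type arrays, and Ear6 and Csta2 on 1 of 3 and P2rx5 and Thbs1 on 2 of 3 CD41-KO arrays. Of the lists, the mast cell, basophil and eosinophil markers had 0 of 14 up and 4 down, or 0 and 5 adjusted over the list alone (shift -0.34, adjusted p = 0.00475, and adjusted p = 0.206 with an estimated correlation), with medians of -0.34, -0.39 and -0.37 on slides 2 to 4. The immediate early list had 0 of 29 up and 5 down, or 1 and 11 adjusted over the list alone (shift -0.27, adjusted p = 0.00475, medians -0.30, -0.30 and -0.28), with Klf6 at -1.12 ± 0.19 and Dusp1 at -0.87 ± 0.14. The cell cycle list had 0 of 42 up and 2 down, or 0 and 7 adjusted over the list alone (shift -0.21, adjusted p = 0.00396, medians -0.26, -0.19 and -0.18). Both had an adjusted p of 0.93 with an estimated correlation. The megakaryocyte and platelet (0 up and 4 down of 40, shift -0.11, adjusted p = 0.0382), erythroid (2 and 2 of 27, shift -0.19, adjusted p = 0.0461), oxidative phosphorylation (0 and 1 of 41, shift -0.15, adjusted p = 0.0149) and ribosomal protein (0 and 0 of 42, shift -0.14, adjusted p = 0.0216) lists lay lower. Adjusted over the list alone, the counts were 2 and 7, 2 and 4, 0 and 1, and 0 and 0, and at limma's unadjusted p under 0.05 the ribosomal protein list had 0 up and 3 down. With an estimated correlation their adjusted p was 0.949, 0.264, 0.956 and 0.956. The stromal list lay higher (3 up and 1 down of 10, or 4 and 1 adjusted over the list alone, shift 0.32, adjusted p = 0.0382, adjusted p = 0.264 with an estimated correlation and 0.0887 with the replicate block), with Sparc at 1.05 ± 0.16. Itgb3 (0.35 ± 0.15), Vwf (0.48 ± 0.17), Selp (-0.30 ± 0.17), Slamf1 (0.00 ± 0.22), Pf4 (-0.48 ± 0.14), Gata1 (-0.32 ± 0.11), Cd48 (0.41 ± 0.20), Flt3 (0.36 ± 0.35) and Mpo (0.04 ± 0.44) did not pass. With the replicate block 5 of these did, Itgb3 (adjusted p = 0.02), Vwf (0.00269), Pf4 (0.00162), Gata1 (0.0149) and Cd48 (0.0266). All 5 passed with array weights (0.0133, 0.00852, 0.00929, 0.00533 and 0.0213). Vwf also passed with normexp (0.0278) and the deposited values (0.033). The mean of the probes of Mpo fell by 0.95, past the test.

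In all, 871 genes were higher and 863 lower in 12-month CD41-KO cells (4584 and 5266 with the replicate block), and 428 changed 2-fold or more. Leaving out any of the 6 arrays compared took the count of 1734 to between 497 (without wild-type replicate 3) and 1029, and it was 8002 with array weights and 808 with only these 2 groups in the fit. The megakaryocyte, erythroid, ribosomal protein and stromal calls were lost after quantile normalization and with array weights. They and that of oxidative phosphorylation were also lost without wild-type replicate 1 and without CD41-KO replicate 2, and that of the immediate early list without wild-type replicate 1. Of 42 called genes chosen by the naming rule, 25 passed in every setting that tested them. With normexp 17 had a log2 fold change smaller by over 1.5 times, among them Scpep1 (1.27), Olfr924 (0.90), Sparc (0.63), Ear6 (-2.93), Dhrs7c (-1.69), Csta2 (-1.06) and Thbs1 (-0.64).

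The fourth comparison asked what age changed in wild-type LT-HSCs. The stress-responsive metallothionein genes Mt2 (5.38 ± 0.18) and Mt1 (3.50 ± 0.21), Selp (4.02 ± 0.17), Nupr1 (2.48 ± 0.10), the clusterin gene Clu (2.17 ± 0.13), Vwf (1.45 ± 0.17) and Itgb3 (0.88 ± 0.15) were higher at 12 months. Selp stood at 0.04 ± 0.20 (SD, n = 3) at 12 months and -3.97 ± 0.21 (SD, n = 3) at 2 months. Cd34, a sialomucin of progenitors, fell by 1.47 ± 0.16. Itga2b differed by -0.29 ± 0.27 (adjusted p = 0.535). The HSC ageing list had 25 of 43 genes up and 2 down, or 30 and 2 adjusted over the list alone (shift 0.65, adjusted p = 1.39e-12, and adjusted p = 0.0887 with an estimated correlation), with medians of 0.69, 0.66 and 0.69 on slides 2 to 4. The eosinophil genes Prg2 (3.40 ± 0.11), Ear6 (5.62 ± 0.37), Epx (1.60 ± 0.21) and Ear2 (1.44 ± 0.12) rose with the mast cell, basophil and eosinophil markers, of which 7 of 14 rose and 0 fell (shift 0.41, adjusted p = 0.00159, and adjusted p = 0.0887 with an estimated correlation, medians 0.40 to 0.46). The wild-type arrays at 2 months differ from those at 12 months in Xist (7.16 ± 0.20) and the Y-linked genes too. Age and this difference cannot be told apart here.

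The cell cycle list had 1 of 42 up and 10 down, or 1 and 12 adjusted over the list alone (shift -0.39, adjusted p = 7.8e-06, and adjusted p = 0.614 with an estimated correlation, slide medians -0.36, -0.32 and -0.25), with Kif23 at -1.18 ± 0.18 and the ribonucleotide reductase gene Rrm2 at -0.87 ± 0.15. The oxidative phosphorylation list had 0 of 41 up and 5 down (shift -0.41, adjusted p = 2.94e-07, and adjusted p = 0.653 with an estimated correlation, slide medians -0.37, -0.29 and -0.27), with Sdhb at -0.71 ± 0.19. The multipotent progenitor list had 0 of 23 up and 7 down, or 1 and 9 adjusted over the list alone (shift -0.42, adjusted p = 0.000976, and adjusted p = 0.259 with an estimated correlation), with Cd53 at -0.67 ± 0.15 and Cd69 at -0.65 ± 0.13. The cytokine receptor (2 up and 6 down of 29, shift -0.30, adjusted p = 0.0308), glycolysis and hypoxia (0 and 2 of 27, shift -0.26, adjusted p = 0.0257) and ribosomal protein (0 and 0 of 42, shift -0.21, adjusted p = 0.0391) lists also lay lower. Adjusted over the list alone, the counts were 3 and 7, 0 and 0, and 0 and 0, and at limma's unadjusted p under 0.05 the ribosomal protein list had 1 up and 2 down. With an estimated correlation their adjusted p was 0.556, 0.653 and 0.794. Ptger4, a prostaglandin E receptor gene, went against its list at 1.35 ± 0.17. The list of sex-linked genes had 1 of 5 up and 4 down (adjusted p = 0.000742, and adjusted p = 0.259 with an estimated correlation).

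Among the remaining highest genes, Myl10 (3.80 ± 0.15) and Olfr126 (3.30 ± 0.62) rose, the scramblase gene Plscr2 was at least 5.29-fold and Sh2d1a at least 2.73-fold higher. Among the lowest, Ssty2 (-9.50), Rbmy (-5.93), Orly (-5.37), Ssty1 (-4.12) and Sly (-3.40) fell, and Ddx3y was at least 13.9-fold, Uty at least 5.16-fold, Chrdl2 at least 4.04-fold, Kdm5d at least 4.00-fold and the Notch target gene Hey1 at least 3.1-fold lower. At 2 months Myl10 was well above background on 2 of 3 and Ear6 and Olfr126 on 1 of 3 arrays, and at 12 months Ssty2 on 1 of 3 and Rbmy on 2 of 3. Slamf1 rose by 0.88 ± 0.22 (adjusted p = 0.0249), while Pf4 (-0.24 ± 0.14), Gata1 (-0.27 ± 0.11), Cd48 (0.20 ± 0.20), Flt3 (0.06 ± 0.35) and Mpo (-0.19 ± 0.44) did not pass. With the replicate block Pf4 (adjusted p = 0.014), Gata1 (0.0203) and the quiescence list (adjusted p = 0.0309, with 1 gene up and 2 down without the block) did, and the mean of the probes of Mpo gave a called rise of 0.98. In all, 2992 genes were higher and 2068 lower at 12 months (8450 and 6032 with the replicate block), 1354 of them by 2-fold or more, and X and Y held 13.2% of the called genes with a mapped probe. Among genes with a symbol 1415 were higher and 1492 lower. The count of 5060 fell to between 2855 and 3337 without wild-type replicate 1 or 3 at 2 months or any wild-type replicate at 12 months, and was 10674 with array weights and 3008 with only these 2 groups in the fit. The calls of the cytokine receptor, ribosomal protein and glycolysis lists were lost without wild-type replicate 1 at 2 months and without wild-type replicate 2 at 12 months. Of 46 called genes chosen by the naming rule, 33 passed in every setting that tested them. With normexp 14 of the 46 had a log2 fold change smaller by over 1.5 times, among them Ear6 (3.03), Myl10 (2.28), Olfr126 (1.07), Ptger4 (0.58) and Slamf1 (0.42). With the mean of probes Ssty1 stood at -6.36 and Sly at -6.73. Sdhb stood at -0.19 without wild-type replicate 1 at 2 months.

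The fifth comparison asked what age changed in CD41-KO LT-HSCs, where all 5 arrays carried Xist. Mt2 (4.99 ± 0.21), Nupr1 (2.22 ± 0.11), Selp (2.01 ± 0.19), the retinaldehyde dehydrogenase gene Aldh1a1 (2.00 ± 0.14), Itgb3 (1.92 ± 0.17) and Vwf (1.26 ± 0.19) were higher at 12 months. Replication and respiration genes were lower, with Mcm2 at -1.61 ± 0.18, Pcna at -1.44 ± 0.15, Cox6a1 at -1.56 ± 0.14 and Cox5a at -1.30 ± 0.16. Pf4 (-1.41 ± 0.15), Gata1 (-1.03 ± 0.12) and Hbb-bt (-3.38 ± 0.27) fell as well, and Ebi3, a cytokine subunit, fell by 3.88 ± 0.22. Itga2b differed by 0.94 ± 0.30 (adjusted p = 0.0356), a call that was lost in 3 alternatives and without any of 5 single arrays. In the cell cycle list 0 of 42 genes rose and 30 fell, or 2 and 33 adjusted over the list alone (shift -1.12, adjusted p = 6.18e-12, and adjusted p = 0.361 with an estimated correlation, medians -0.98 and -0.93 on slides 2 and 3). In the oxidative phosphorylation list 0 of 41 rose and 34 fell, or 0 and 35 adjusted over the list alone (shift -1.05, adjusted p = 3.75e-14, and adjusted p = 0.441 with an estimated correlation, medians -0.91 and -0.92). In the HSC ageing list 22 of 43 rose and 2 fell, or 25 and 3 adjusted over the list alone (shift 0.52, adjusted p = 9e-07, and adjusted p = 0.322 with an estimated correlation, medians 0.70 and 0.71).

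The multipotent progenitor list had 0 of 23 up and 11 down, or 0 and 12 adjusted over the list alone (shift -0.67, adjusted p = 0.0019, and adjusted p = 0.322 with an estimated correlation), with Cd34 at -1.86 ± 0.18. The interferon list had 2 of 36 up and 14 down (shift -0.50, adjusted p = 0.00177, and adjusted p = 0.50 with an estimated correlation), with Oasl2 at -1.48 ± 0.17 and Stat2 at -1.25 ± 0.15. The ribosomal protein (0 up and 13 down of 42, shift -0.56, adjusted p = 1.09e-05) and glycolysis and hypoxia (1 and 11 of 27, shift -0.53, adjusted p = 0.0117) lists, with 0 and 11, and 2 and 11, adjusted over the list alone, had an adjusted p of 0.563 with an estimated correlation. The cytokine receptor list (2 up and 12 down of 29, shift -0.51, adjusted p = 0.0117, and adjusted p = 0.441 with an estimated correlation) held Csf2rb2 at -1.59 ± 0.17 and Notch2 at -1.49 ± 0.21. Tdrd9 (3.69 ± 0.69), Olfr214 (2.65 ± 0.23) and Hoxb8 (2.62 ± 0.47) were also among the 10 highest genes, with Togaram2, whose probe in the fit was well above background on 0 of 2 arrays at 2 months, and Islr (-3.07 ± 0.28) and Arhgap30 (-2.76 ± 0.27) were among the lowest. Tdrd9 was well above background on 1 of 2 arrays at 2 months, and Islr on 1 of 3 and Arhgap30 on 2 of 3 at 12 months. Olfr881 was at least 10.5-fold, Plscr2 at least 5.41-fold, Resp18 at least 2.76-fold, Trmt9b at least 2.55-fold and Chrna4 at least 1.74-fold higher. Hnf4a was at least 6.67-fold, Ska1 at least 4.84-fold, Tigd3 at least 3.83-fold, Rfx8 at least 3.62-fold, Phlda2 at least 3.05-fold and Sp3 at least 1.71-fold lower. Slamf1 (-0.02 ± 0.24), Cd48 (0.53 ± 0.22), Flt3 (0.70 ± 0.39) and Mpo (-0.09 ± 0.50) did not pass. With the replicate block Cd48 (0.64, adjusted p = 0.00335), the long-term HSC list (adjusted p = 0.0414) and the neutrophil markers (0.0395) did, of which 5 of 40 and 5 of 11 genes rose and 14 and 0 fell without it, and the glycolysis call was lost without CD41-KO replicate 1 at 2 months. Flt3 passed with the slide as a random block (0.54, adjusted p = 0.0471) and Mpo with the mean of its probes (-1.47, adjusted p = 0.0022). With normexp 18 of 57 called genes chosen by the naming rule had a log2 fold change smaller by over 1.5 times, among them Tdrd9 (1.72), Hoxb8 (1.37), Olfr214 (1.36), Arhgap30 (-1.80) and Islr (-1.29). Notch2 stood at -0.77 with the mean of its probes.

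In all, 5305 genes were higher and 6407 lower at 12 months in CD41-KO cells (11702 and 9112 with the replicate block), of which 3196 changed 2-fold or more, and 5170 were called without CD41-KO replicate 1 at 2 months. Among genes with a symbol 2195 were higher and 4811 lower. Genes taken as silent in blood, which are part of the background of the list tests here too, had a median of 0.34, with 1368 of 5854 higher and 326 lower. The median was 0.17 for age in wild-type cells (598 higher and 135 lower), 0.14 for the interaction (286 and 141), and -0.11 (246 and 299) and 0.05 (188 and 83) for genotype at 2 and 12 months. Across genes, which are not independent replicates, fold changes with age correlated between wild-type and CD41-KO cells at r = 0.29 (rho = 0.45), with no array in common. Higher in both were 1329 genes, against 472.5 from independent lists, lower in both were 1332, against 394.4, and 254 went opposite ways, against 897.3.

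**Figure D3:**
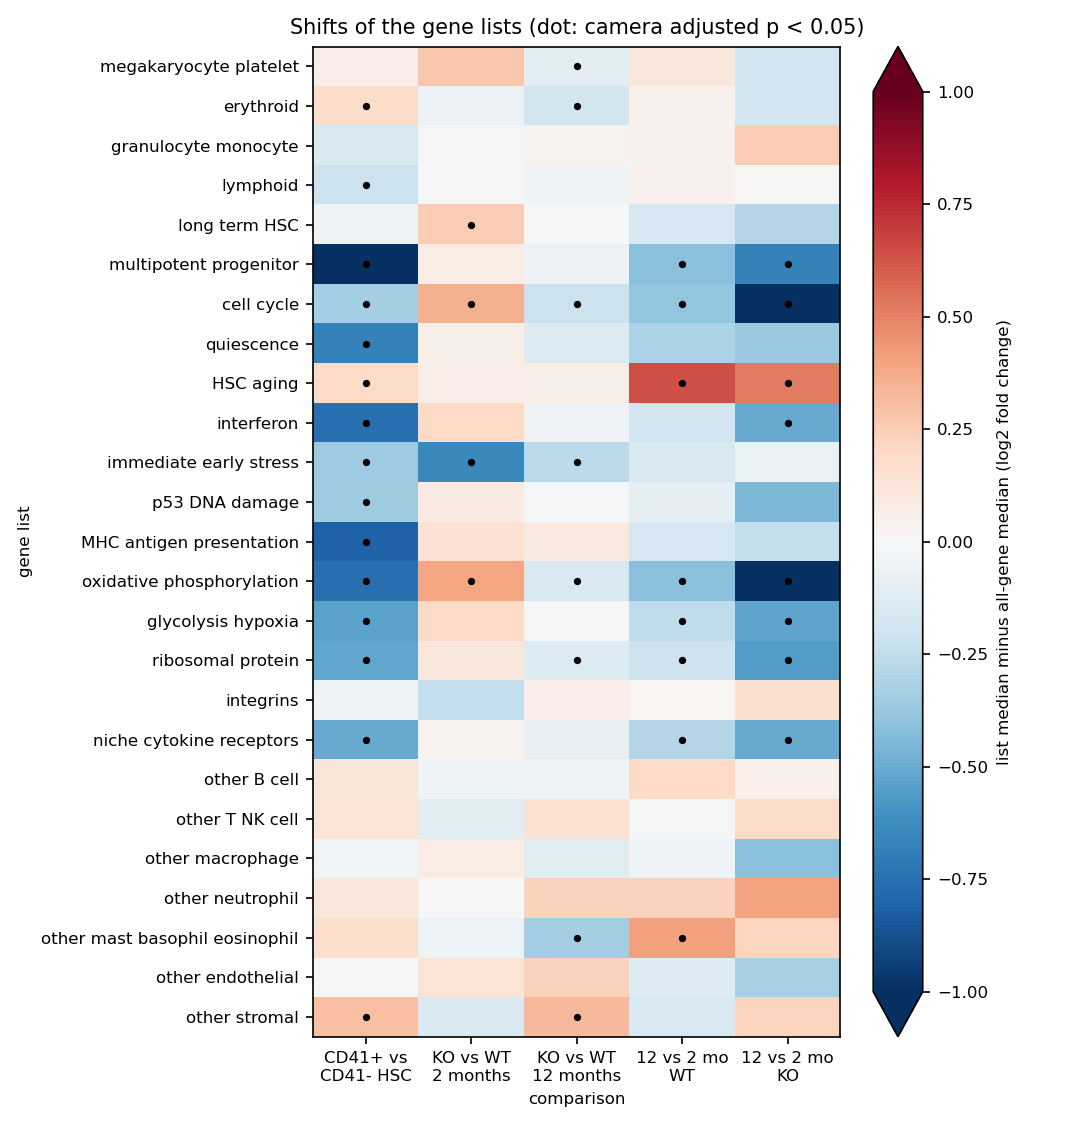
Median log2 fold change of each gene list minus that of all genes (colour, scale ending at -1 and 1) for 25 lists (rows) in 5 comparisons (columns), with dots where camera's adjusted p passed 0.05. The multipotent progenitor list stood at -1.62 in the CD41 sort, and the HSC ageing list at 0.65 and 0.52 with age in wild-type and CD41-KO cells.

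The effect of genotype was then compared between ages by the interaction, for which 1311 genes had a more positive CD41-KO effect at 12 months and 1940 a more negative one (5176 and 7110 with the replicate block). Of the lists 9 passed, 3 up and 6 down. The cell cycle list (0 up and 12 down of 42, or 1 and 22 adjusted over the list alone, shift -0.58, adjusted p = 1.28e-06) and the oxidative phosphorylation list (0 and 11 of 41, or 0 and 17 adjusted over the list alone, shift -0.53, adjusted p = 2.14e-07) had a more negative effect at 12 months, with an adjusted p of 0.675 for both with an estimated correlation. Of the 20 genes chosen by the naming rule, with an adjusted p of at most 0.0457, the Y-linked Ssty2 (9.07), Rbmy (6.61), Orly (5.56) and Ssty1 (4.48) had a more positive effect, and Xist (-7.88), Ear6 (-5.68), Myl10 (-3.93), Olfr126 (-3.67) and Abcb9 (-3.44) a more negative one. With normexp 15 of the 20 were smaller by over 1.5 times, among them Ear6 (-3.08), Myl10 (-2.43), Olfr126 (-1.30) and Abcb9 (-0.86). Ssty1 stood at 6.74 with the mean of its probes. Of those with a size, only Orly, Ssty1 and Xist were well above background on every LT-HSC array, and Ssty2 was so on 1 of 3 arrays of either genotype at 12 months. The remaining 11 were not well above background on any array of at least 1 of the 4 groups, so no size or order is given. They were Ddx3y, Uty, Kdm5d, Olfr881, Resp18 and Zfp105, with a more positive effect, and Atg9b, Rpl39l, Kbtbd7, Zfp418 and Nucb2, with a more negative one. The effect of genotype on Prg2 differed by -2.84 (adjusted p = 1.04e-05), on Selp by -2.01 (adjusted p = 0.00192) and on Itgb3 by 1.04 (adjusted p = 0.0238). For Itga2b itself the difference of 1.23 did not pass (adjusted p = 0.0855), and for Gdpd3 it was -0.02 (adjusted p = 0.992). The wild-type arrays at 2 months enter this comparison, and they differ from all other LT-HSC arrays in sex-linked genes. That difference cannot be told apart from the interaction. X and Y held 10.9% of its called genes with a mapped probe. Across genes, fold changes with genotype at 2 and 12 months correlated at r = 0.05 (rho = -0.05). Higher at both ages were 219 genes, against 64.3 from independent lists, lower at both were 151, against 38.3, and 184 went opposite ways, against 102. The called count of 3251 was 854 without CD41-KO replicate 1 at 2 months, 2167 with arrays centred on the median, an alternative chosen after seeing the data, and 6558 with array weights.

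The genes that separated CD41-positive from CD41-negative HSCs were followed in LT-HSCs, as 100 genes per direction. The medians that follow are not relative to all genes. The 100 genes lower in CD41-positive HSCs had a median of 0.35 in CD41-KO over wild-type cells at 2 months (15 up and 1 down, adjusted p = 1.35e-07) and of -0.28 at 12 months (3 up and 13 down, adjusted p = 4.52e-07). With age the same set had a median of -0.12 in wild-type cells (2 up and 12 down, adjusted p = 0.000379) and -0.70 in CD41-KO cells (3 up and 69 down, adjusted p = 2.77e-18). For the interaction it was -0.59 (2 up and 25 down, adjusted p = 2e-12). With an estimated correlation none of these 5 passed, at p = 0.296, 0.319, 0.468, 0.107 and 0.179. Genes taken as silent in blood, whose median was above 0 in the CD41 sort, moved against this set in each of the 5. Their medians were -0.11, 0.05, 0.17, 0.34 and 0.14 in the same order. Whether the set moved apart from the shift of the silent genes was not tested. Of the 100 genes higher in CD41-positive HSCs 86 were tested, and they passed camera's test in none of the 5 comparisons, with adjusted p from 0.074 to 0.747 and 1 unadjusted p under 0.05, of 0.0444 at 2 months. With the replicate block in the LT-HSC arrays, an alternative chosen after seeing the data, they passed for age in wild-type cells (median -0.12, adjusted p = 0.039). Without the block and with an estimated correlation, camera's unadjusted p for them in that comparison was 0.107. Across genes, the fold changes of the CD41 sort correlated with those of age in wild-type LT-HSCs at r = 0.16 (rho = 0.26). Genes taken as silent in blood had a median above 0 in both (0.26 and 0.17), and no correlation of fold changes was redone without them.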

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

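The tests on a single mislabelled array, the slide and male mice for the sex-linked genes, on sex acting on autosomal genes, and on unspecific hybridisation were chosen only after the result was seen. The results below were picked because the difference of CD41-KO from wild-type cells changed between 2 and 12 months by limma's interaction test. Each value is the log2 difference at 12 months minus that at 2 months. A negative value can come from a gene that was higher in CD41-KO cells at 2 months, lower at 12 months, or both, and every one rests in part on the 3 wild-type arrays at 2 months, which differ from all other LT-HSC arrays in sex-linked genes.

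The median of the cell cycle list (0 up and 12 down of 42, or 1 and 22 adjusted over the list alone, adjusted p = 1.28e-06, and adjusted p = 0.675 with an estimated correlation) was -0.60, with Gins2 (-1.25), Nusap1 (-1.15), Pcna (-1.10), Cdca8 (-1.06), Dut (-0.68), Kif11 (-0.62) and Ccne1 (-0.61). The median of the oxidative phosphorylation list (0 up and 11 down of 41, or 0 and 17 adjusted over the list alone, adjusted p = 2.14e-07, and adjusted p = 0.675 with an estimated correlation) was -0.55, with Cox6a1 (-1.20), Cox7b (-1.20), Sdhd (-1.06), Cox5a (-0.98), Uqcrfs1 (-0.89), Ndufc1 (-0.82), Ndufa5 (-0.75), Ndufb8 (-0.61) and Cox6c (-0.60). The ribosomal protein list (0 genes up and 1 down of 42, adjusted p = 0.00808, and adjusted p = 0.744 with an estimated correlation) stood at -0.26 with Rpl4 (-0.78).

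The megakaryocyte and platelet list (1 up and 9 down of 40, or 2 and 16 adjusted over the list alone, adjusted p = 0.00808, and adjusted p = 0.675 with an estimated correlation) had a median of -0.44, with Selp (-2.01), Thbs1 (-1.97), Fli1 (-1.30), Trpc6 (-1.24), Pf4 (-1.18) and Gata1 (-0.76), while Itgb3 (1.04) went the other way. The erythroid list did not pass (1 up and 5 down of 27, adjusted p = 0.392), and of its genes Hbb-bt (-3.22) and Klf1 (-1.59) were lower and Trim10 (0.87) higher. Medians were -0.26 for the long-term HSC list (0 up and 4 down of 40, adjusted p = 0.0485, and adjusted p = 0.73 with an estimated correlation), which holds Ctnnal1 (-1.08), and -0.28 for the interferon list (2 up and 7 down of 36, or 2 and 8 adjusted over the list alone, adjusted p = 0.0375, and adjusted p = 0.675 with an estimated correlation), with Oasl2 (-1.12) and Stat2 (-1.05). The receptor genes Notch2 (-1.33), Csf2rb2 (-1.31) and Ptger4 (-1.04) and the progenitor gene Ramp1 (-0.69) were lower too, but the cytokine receptor (1 up and 3 down of 29, adjusted p = 0.214) and multipotent progenitor (0 and 2 of 23, adjusted p = 0.394) lists did not pass. The immediate early list (5 up and 1 down of 29, adjusted p = 0.0136, and adjusted p = 0.713 with an estimated correlation) stood at 0.26 with Junb (1.19) and Atf3 (1.62), and the stromal list (2 up and 0 down of 10, or 4 and 1 adjusted over the list alone, adjusted p = 0.0229, and adjusted p = 0.557 with an estimated correlation) at 0.45 with Cxcl12 (1.93) and Lepr (1.25).

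Other genes with a more negative effect at 12 months were Myl10 (-3.93), Olfr126 (-3.67), Abcb9 (-3.44), Emilin2 (-3.11) and Ebi3 (-1.29), and Olfr877 (2.20) and Olfr214 (1.15) had a more positive one. Of the wild-type arrays at 2 months, 2 of 3 measured Myl10 well above background, and 1 of 3 Olfr126, Abcb9, Ear6 and Thbs1, and of the CD41-KO arrays at 12 months 2 of 3 measured Olfr126 and Thbs1 and 1 of 3 Abcb9 and Ear6.

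The genes of this paragraph were not well above background on any array of at least 1 of the 4 groups, so each number is limma's fitted value, which gives no measured size and no order. Negative values were fitted for Alpl (-1.93), Atg9b (-3.65), Egfl6 (-2.73), Glod5 (-1.70), Islr (-1.39), Kbtbd7 (-3.47), Ms4a2 (-1.81), Nucb2 (-3.32), Rfx8 (-1.77), Rpl39l (-3.52), Ska1 (-2.67), Slc8a2 (-2.11), Sp3 (-2.48), Tigd3 (-2.72) and Zfp418 (-3.39). Positive values were fitted for Arhgef17 (1.62), Chrdl2 (3.30), Chrna4 (2.65), Etnppl (2.62), Hey1 (1.98), Olfr881 (4.81), Resp18 (3.90) and Zfp105 (3.38), and for the Y-linked Ddx3y (5.90), Kdm5d (4.15) and Uty (4.42). The list of sex-linked genes (Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, 4 up and 1 down, adjusted p = 0.0022, and adjusted p = 0.557 with an estimated correlation) had a fitted median of 4.15, which is the value of Kdm5d and gives no size either.

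Xist stood at -7.88, and of Y-linked genes outside that list Ssty2 stood at 9.07, Rbmy at 6.61, Orly at 5.56 and Ssty1 at 4.48. A single mislabelled array is argued against, since 3 wild-type arrays at 2 months had Xist below every other LT-HSC array, and a slide effect too, since these lay on 3 slides. Male mice in the wild-type pools at 2 months and female mice elsewhere are a candidate explanation, as 4 of the 4 Y-linked genes set for the test (Ddx3y, Kdm5d, Uty and Eif2s3y) were higher on every one of these arrays than on all others. Copy number of X and Y genes does not account for most differences between genotypes at 2 months, because 11.8% of the called genes with a mapped probe lay on X or Y. Whether sex acted on the autosomal ones cannot be told apart from the loss of CD41 and from age, as 0 wild-type arrays at 2 months carried Xist like the other arrays, and the biological difference named by the labels stays open.

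Ear6 (-5.68), Prg2 (-2.84), Hdc (-1.71), Epx (-1.55) and Ear2 (-1.03) were more negative at 12 months, but the list of mast cell, basophil and eosinophil markers, which holds these genes except Ear6, did not pass (1 up and 5 down of 14, adjusted p = 0.106, and 0.28 with the replicate block). A slide effect is argued against, since Prg2 was lower in the CD41-KO array on 3 of 3 slides (-2.86, -2.87 and -2.77). Eosinophil-lineage cells in the wild-type sorts at 12 months remain open. Of the 12 genes of an eosinophil list written before the test, 7 were higher on every wild-type than on every CD41-KO array at that age. This lay between the 9 or more they would need and the bound against them. The count cannot decide, because the 7 include Prg2, Epx, Ear2 and Ear6, whose fall in this same comparison had raised the question. The rest of the 7 were Ear10, Il5ra and Cebpe. Of all tested genes, 26.0% had groups that did not overlap at 12 months, in either direction. Prg2, Epx, Ear2 and Ear6 passed the test, while the remaining 8, Prg3 (-0.71), Ear1 (-0.03), Ear10 (-0.13), Alox15 (0.44), Siglecf (-0.16), Ccr3 (0.14), Il5ra (-0.30) and Cebpe (-0.57), did not, though with the replicate block Prg3 (adjusted p = 0.0154) and Il5ra (0.0167) did. The gate on lineage-negative cells would remove mature eosinophils, 5 of the 12 genes also stand in other lists (Prg2, Prg3, Epx, Ear2 and Cebpe), and a change of these genes within HSCs with CD41 status or age was not tested apart.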

How the results depend on the processing

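The counts with arrays centred on the median of the tested genes, with a fold change of 2 or more and without genes on X or Y, and the block applied to the LT-HSC arrays alone for the genes of the CD41 sort, were chosen only after the result was seen. Under the alternatives other than centring that changed scaling, background correction, the dim-probe filter, the probes of a gene or, by trend and robust eBayes, the variance prior, each count of called genes stayed within 1.5 times its value. Of 83 called genes named in the CD41 sort, 83 passed in every setting that tested them, against 24 of 42 and 25 of 42 for genotype at 2 and 12 months, 33 of 46 and 50 of 57 for age in wild-type and CD41-KO cells and 16 of 20 for the interaction. A gene that a filter on dim probes removed was not tested in that setting, which these counts do not hold against it. Of the 20 genes of the interaction only Orly, Ssty1 and Xist were well above background on every LT-HSC array. The log2 fold change of the called genes was smaller by over 1.5 times for 14, 16, 17, 14, 18 and 15 of them with normexp and for 12, 15, 16, 14, 18 and 15 with the deposited values. It moved that far for 3, 2, 1, 5, 1 and 1 with the mean of probes and for 2 and 1 genes for age in wild-type and CD41-KO cells without an array. In the LT-HSC set 82.7% to 93.3% of spots were well above background, against 96.0% to 98.5% in the CD41 sort, and a gene not well above background in a group has only a bound there. Where a count or call changed below and no construction explains it, the cause was not tested. The 2-group fit does not apply to the interaction, and a slide block not to the CD41 sort on 1 slide. Where leaving out an array left 1 CD41-KO array at 2 months, it was assumed to vary like the other groups.

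With array weights, 8002 genes were called for genotype at 12 months, 10674 for age in wild-type cells and 6558 for the interaction. With only the 2 groups compared, which leaves fewer degrees of freedom, there were 1043 and 808 for genotype at 2 and 12 months and 3008 for age in wild-type cells. Centring gave 1147 for genotype at 12 months and 2167 for the interaction. A fold change of 2 or more, which only removes calls, left 2221 in the CD41 sort, 1379 and 428 for genotype at 2 and 12 months, 1354 and 3196 for age in wild-type and CD41-KO cells, and 1879 for the interaction. Without X and Y genes in the fit and adjustment the counts were 19849, 3307, 1704, 4180, 11243 and 2754 in the same order. Among genes with a symbol, 6139 were higher and 5408 lower in the CD41 sort. For genotype these counts were 1558 and 663 at 2 months and 404 and 556 at 12 months. For age they were 1415 and 1492 in wild-type and 2195 and 4811 in CD41-KO cells, and for the interaction 547 and 1302. Called lists numbered 4 for genotype at 12 months with quantile normalization and 4 with array weights, and 8 for genotype at 2 months with the mean of a gene's probes. With an estimated correlation camera called 0 lists in each of the 6 comparisons, with 7, 1, 3, 4, 4 and 2 at an unadjusted p under 0.05.

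With the replicate number as a block, 12366 and 9850 genes were called for genotype at 2 and 12 months, 14482 and 20814 for age in wild-type and CD41-KO cells and 12286 for the interaction, and 9 lists for genotype at 2 months. The slide as a random block gave 12557, 10331, 14412, 20505 and 12490 genes and 9 lists. Removing the spread between slides leaves a smaller residual, and besides the calls printed with the results the block added 9 smallest-p members of called lists for genotype at 12 months and 6 for age in wild-type cells, and it changed no other call of a list or gene reported here. In the CD41 sort the deviations of same-numbered arrays correlated at 0.467, 0.0396 and 0.496 for replicates 1, 2 and 3. Whether the numbers pair arrays there is thus not settled. The block gave 25118 calls (16755 higher and 8363 lower), lost the erythroid and stromal lists (adjusted p = 0.0822 and 0.0895), and added the megakaryocyte list (0.0486) and the mast cell, basophil and eosinophil markers (0.044).

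Mpo, which did not pass with its brightest probe, was called at 1.5 and -0.95 for genotype at 2 and 12 months and at 0.98 and -1.47 for age in wild-type and CD41-KO cells with the mean of its probes. The correlation of age effects between genotypes, 0.29, was 0.33 with normexp and with the deposited values, and 0.41 with probes well above background on all arrays, where that of genotype effects between ages was 0.0202.

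The 100 genes higher in CD41-positive HSCs had no stable direction. Their median passed camera's test for genotype at 2 months with probes well above background on all arrays (-0.16), the mean of probes (-0.22) and 2 groups (-0.15). For age in wild-type cells it passed with normexp (-0.13), probes well above background on all arrays (-0.20), 2 groups (-0.16) and the replicate block in the LT-HSC arrays with the sets unchanged (-0.12, adjusted p = 0.039, against 0.0814 where the block also remade the sets). Without CD41-positive replicate 3 it passed for both (-0.16 and -0.14), as it did without wild-type replicate 1 at 2 months (-0.28 and -0.20). The adjusted p of the passing settings were 0.00388 to 0.0491. The sign of camera's statistic turned for genotype at 12 months with trend and robust eBayes (median 0.00498), the replicate block that also remade the sets (-0.0490) and 200 genes (0.0188), and for age in wild-type (0.0291) and CD41-KO cells (0.25) with 200 genes. It also turned for age in CD41-KO cells without CD41-negative replicate 1 (0.26), for that (0.25) and genotype at 12 months (0.0024) without replicate 2, and for age in CD41-KO (0.21) and wild-type cells (-0.0095) and the interaction (-0.14) without replicate 3.

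Leaving out 1 array at a time gave 16160 to 20341 genes and 13 to 17 lists in the CD41 sort, 988 to 3878 and 4 to 10 for genotype at 2 months, 497 to 1721 and 2 to 8 at 12 months, 2855 to 4925 and 7 to 12 for age in wild-type cells, 5170 to 12193 and 7 to 9 in CD41-KO cells, and 854 to 3217 and 6 to 9 for the interaction. The interaction count was 1739 without CD41-KO replicate 2 and 1746 without wild-type replicate 3 at 2 months, and 1786, 1688 and 1725 without wild-type replicate 1 or 3 or CD41-KO replicate 3 at 12 months. Medians of the genes higher in CD41-positive HSCs ran from -0.28 to 0.0055, -0.25 to 0.0024, -0.20 to -0.0075, -0.0370 to 0.26 and -0.17 to 0.12 in the 5 LT-HSC comparisons. Those of the genes lower in CD41-positive HSCs ran from 0.26 to 0.47, -0.35 to -0.21, -0.20 to -0.04, -0.84 to -0.57 and -0.69 to -0.46.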

Other observations

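The correlation of the CD41 sort with age in CD41-KO cells, the counts by chromosome of genes called at both ages, the test on unspecific hybridisation, the split of silent genes by family and the correction that added intergenic RNAs to the silent genes were chosen only after the result was seen. Of the genes called between CD41-KO and wild-type cells at both ages, 370 moved the same way and 184 opposite ways, against 102 opposite from independent lists. Whether these differences follow from the loss of CD41 or from other differences between the mice was not tested. The 370 included the phosphodiesterase gene Gdpd3 (5.51 at 2 months and 5.50 at 12 months) and the matrix gene Emilin2 (3.75 and 0.64). Chromosome 11, which carries Itga2b, held 54 of the 370, or 2.39% of its 2260 tested genes, the highest share of an autosome. The next were 2.23% on chromosome 13 and 2.20% on chromosome 16, and the other autosomes lay between 0.30% and 1.62%. Within 10 Mb of Itga2b 8 of 538 tested genes, Itga2b itself included, were among the 370 (1.49%), against 1.10% elsewhere.

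Across genes, which are not independent replicates, the fold changes of the CD41 sort correlated with those of age in CD41-KO LT-HSCs at r = 0.49 (rho = 0.50), with no array in common. Higher in both were 2989 genes, against 1961 from independent lists, lower in both were 3904, against 1403, and 972 went opposite ways. Genes taken as silent in blood had a median above 0 in both comparisons (0.26 and 0.34). The correlation and these counts include them and were not redone without them, so they do not show a likeness particular to CD41.

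Probes of genes taken as silent in blood gave signal well above background on 97.8% of spots of the CD41 sort arrays. These genes, which include intergenic RNAs not tested for silence in HSCs, stood higher in CD41-positive HSCs (2957 of 5996 higher, 466 lower). The 75th percentile scaling, array brightness and one common shift are each argued against as the whole cause, since the median difference stayed at 0.24 after quantile normalization, each CD41-positive array lay at least 0.19 above each CD41-negative one, and 31.5% of silent genes still passed after each array was centred on their median (0.24, 0.24 and 33.0% without intergenic RNAs). Genomic DNA in the amplified material remains open, because X-linked minus autosomal silent probes differed by 0.36 ± 0.039 (bootstrap SE) between arrays with and without Xist at 2 months, between the 0.5 it would need and the bound of 0.2 against it, but the first run, which left out intergenic RNAs through a naming error, gave 0.83 ± 0.21 from 8 X-linked probes, inside the range set for it, and 0.93 ± 0.24 for age in wild-type cells. With intergenic RNAs the contrasts did not match, with 0.14 ± 0.034 for age in wild-type cells, where Xist differed too and the value lay below 0.2, and -0.16 ± 0.037 for age in CD41-KO cells and -0.03 ± 0.018 for genotype at 12 months, where all arrays carried Xist (0.11 ± 0.15 and 0.14 ± 0.10 from the 8 probes). Unspecific hybridisation stays open too, as 69.4% of spots of 18 Y-linked probes were well above background on the arrays with Xist, against 89.8% for autosomal silent probes and 98.1% for the Y-linked ones on the wild-type arrays at 2 months, and the row on the slide cannot be told apart from CD41 status, untested as a biological explanation.

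With 6 arrays split 3 against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 split with the most called genes in the CD41 sort (20876 genes), for genotype at 12 months (1734) and for age in wild-type cells (5060), and the highest of the other splits called 0 genes with limma in each. The other splits mix the real groups, whose difference then adds to the spread within each side. Their 0 calls therefore give no rate of false calls. At an unadjusted p under 0.05 the other splits gave 60 to 2235 genes in the CD41 sort, against 22804, 214 to 2971 for genotype at 12 months, against 6896, and 172 to 3760 for age, against 9681. Among splits that part all same-numbered pairs as the real one does, the others gave 214 to 231 for genotype at 12 months and 172 to 308 for age. A group of 2 arrays left genotype at 2 months and age in CD41-KO cells without such splits.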
